A study of Mus musculus with 30 samples.

How the data were processed

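RNA from kidney and pancreas of C57BL/6 mice was sequenced by the submitters as stranded poly(A) libraries from 1 µg RNA with 8 PCR cycles; the labels give RNA integrity numbers of 7.4 to 9.4 (mean 8) and over 24 M mapped reads per sample. Gene values were deposited by the authors as FPKM, one table per tissue. The submitters' notes name FastQC, TopHat2 2.0.10, Bowtie 1.0.0, SAMtools 0.1.19 and Cufflinks 2.2.1 and the mouse build mm10, with no roles. Whether a further scaling between libraries was applied is not stated. Read counts were not used here, so the depth of single genes is unknown and no interval or floor was computed from counts. Gene positions and lengths were taken from GENCODE M21 (GRCm38).

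Samples were grouped by tissue and genotype as labelled, 5 mice in each of 6 groups. The third pancreas group is labelled p53 KO with no mention of i4F. In each tissue the 3 genotypes were compared pairwise. The tests, the gene lists, the rule for genes to name and most other settings tried were set before the data were examined.

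Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with a trend) on the 15 libraries of a tissue. Genes with at least 1 FPKM in at least 5 of the 15 libraries were tested. Tests were two-sided with a Benjamini-Hochberg adjusted p under 0.05, and no covariate was used. The difference between tissues was tested as an interaction over all 30 libraries. Because FPKM are relative to the reads of a library, each comparison was also fitted after median-of-ratios scaling, which divides each library by its median ratio to the geometric mean over the libraries of the tissue; the text calls these values scaled. By Xist and Ddx3y, i4F replicate 3 is male in kidney and female in pancreas, so that number does not name the same mouse in both tissues. The other numbers agree in sex between the tissues, so a shared mouse stays open for them. The interaction took all 30 libraries as independent. With genotype and replicate number as a block across tissues, 11278 genes passed for the p53 KO label (consensus correlation 0.0354). Whether replicate numbers pair libraries within a tissue is not stated. In kidney p53 KO against i4F 3 of 5 pairs had r over 0.1 (-0.0789 to 0.291, in the other comparisons at most 2 of 5), and the number was tried as a block.

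Gene lists were 38 sets holding 932 different genes, drawn up from textbook knowledge as markers and pathways. Lists with at least 4 tested members, 34 in each tissue, were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with limma's fry. For fry, all members moving one way on balance counts, without comparison with other genes. Members past the threshold were counted over all genes and adjusted over the list alone. Lists overlap in part, so their results are not independent.

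The genes to name were set by rule: Trp53, Cdkn2a, Cdkn1a, Pou5f1, Sox2, Klf4, Myc, Nanog and Il6 always. To these were added the 6 largest rises and 6 largest falls among called genes with no overlap of groups and at least 2 FPKM in the higher group, and up to 3 called members of each list with the smallest p. The text names a part of these, picked after their values were seen. Members named because a list had 5 or fewer calls lie partly outside the rule and were chosen after their values were seen: Plk2, Zmat3 and Ctrb1 in kidney p53 KO against i4F Ink4a/Arf KO, and Egf, Vegfa, Krt23, Il11ra1, Lifr, Fgl2, Pim3, Tfcp2l1, Lefty1, Gata4, Atf3, Atm, Igfbp5, Herpud1, Edem1 and Sel1l in pancreas p53 KO against i4F. Results of single members of some lists are not reported here. Some genes are listed at 0 in single libraries and at 10000 FPKM or more in others, and no change was read from Cela2a or Pnlip in the pancreas.

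The resemblance of both knockouts was set against 100 simulations of unchanged groups and against 20 splits of the 5 i4F libraries. Relations across mice used Pearson's r and Spearman's rho with permutation tests of 100000 resamples, two-sided. The plan had been to use all 15 pancreas libraries and 4 relations; as the pancreas libraries labelled p53 KO form a separate cluster, 10 libraries and 3 relations were used, a choice made after the data were seen. Nanog against Il6 was not tested in the pancreas, where Il6 was listed at 0 in most of the remaining libraries.

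Other settings chosen beforehand were a pseudocount of 0.1, no filter, a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, array weights, robust variances, replicate number as a block, Xist level as a covariate, a fit of only the 2 groups compared, and leaving out each library in turn. Settings added after the data were seen left out genes listed at 0, female mice, or kidney libraries above 100 FPKM of Clps, or used Clps as a covariate. Each comparison was also repeated on 100 splits of its libraries drawn at random, the real one included.

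The procedure was tested on simulated data with the spread of each gene in these libraries, drawn independently for each gene and library. Of 100 genes changed by 1 on the log2 scale 82 were recovered in kidney and 57 in pancreas, and of 100 changed by 2, 99 and 98 were recovered. False calls were 13 of 12271 genes in kidney and 8 of 9086 in pancreas, and an unchanged comparison gave 0 calls. The simulation held no variation shared between genes and no difference in spread between groups, so it does not give the rate of false calls in the real libraries. For the difference between tissues 34 of 94 genes changed by 1 and 84 of 91 changed by 2 were recovered. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15 with pandas 2.3.3.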

Results

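Poly(A) RNA was sequenced from kidney and pancreas of C57BL/6 mice that carried i4F, a cassette from which doxycycline induces the reprogramming factors Oct4 (gene Pou5f1), Sox2, Klf4 and Myc. The mice drank 0.2 mg/ml doxycycline for 7 days. In each tissue 5 libraries came from i4F mice, 5 from i4F mice without Ink4a/Arf (the Cdkn2a locus) and 5 from mice labelled as without p53 (gene Trp53), which makes 30 libraries in 6 groups. The pancreas labels of the last group read p53 KO without naming i4F. Gene levels were deposited as FPKM, and the labels give over 24 M mapped reads per sample; read counts were not used here, so the depth behind a single gene is unknown. Kidney libraries held 11539 to 12473 genes at 1 FPKM or more. Pancreas libraries held 6596 to 9852 such genes in i4F, 6867 to 7892 in i4F Ink4a/Arf KO and 10507 to 13194 in the libraries labelled p53 KO. All fold changes are on the log2(FPKM + 1) scale, which understates them for genes near 1 FPKM. Means are given in FPKM with their SD over 5 mice.

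The first question was whether the deleted genes and the induced factors differed between genotypes. In the kidney, Trp53 (chromosome 11, 69580359 to 69591873, mm10) measured 16.4 ± 2.2 FPKM in i4F, 15.9 ± 1.90 in i4F Ink4a/Arf KO and 7.04 ± 2.12 in i4F p53 KO. The 5 p53 KO values lay below every i4F value (log2 fold change -1.14, SE 0.15, adjusted p = 0.00547). In the pancreas, Trp53 was not lower in the libraries labelled p53 KO: it measured 3.4 ± 2.14 FPKM in i4F, 2.89 ± 0.799 in i4F Ink4a/Arf KO and 15.6 ± 7.12 in p53 KO. Of the 5 values 4 lay above every i4F value, and this rise of 1.91 (SE 0.33, adjusted p = 3.69e-05) ended after scaling to the median gene (0.16, adjusted p = 0.388). Cdkn2a (chromosome 4, 89274471 to 89294653) was near 0 in i4F kidney (0.0427 ± 0.0395 FPKM) and i4F pancreas (0.0773 ± 0.138 FPKM), too low for its loss to be seen in i4F Ink4a/Arf KO. It measured 6.58 ± 5.82 FPKM in the pancreas libraries labelled p53 KO and was below the filter for testing in both tissues.

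The group means of the 4 induced factors were highest in p53 KO in both tissues, but single kidney libraries overlapped, as in Pou5f1 with 0.65 FPKM in p53 KO replicate 2 and 5.4 in i4F replicate 4. FPKM per gene does not separate cassette transcripts from those of the mouse's own Pou5f1, Sox2, Klf4 and Myc. In the pancreas, Pou5f1 measured 56.9 ± 30.9 FPKM in p53 KO and 0.668 ± 0.524 in i4F, a log2 fold change of 5.01 (SE 0.37, adjusted p = 1.80e-08). Sox2 changed by 3.78, Klf4 by 3.61 and Myc by 3.22, and all 5 p53 KO values of each lay above every i4F value. After scaling the changes were 3.48, 2.44, 1.83 and 1.29, all with adjusted p under the threshold. In the kidney Pou5f1 measured 6.72 ± 5.84 FPKM in p53 KO and 1.37 ± 2.31 in i4F, and the difference of 1.74 (SE 0.66) did not pass the test (adjusted p = 0.266). Kidney Sox2, Klf4 and Myc had adjusted p values of 0.297, 0.246 and 0.274, and 2 of 5 p53 KO values of each lay above every i4F value. The list of the 4 factors was called higher in kidney p53 KO (4 rose adjusted over the list alone, 0 over all genes; adjusted p = 0.00226). That list call was lost with an estimated correlation (adjusted p = 0.521 with an estimated correlation). Nanog, a pluripotency gene, measured 1.45 ± 1.71 FPKM and Il6, an inflammatory cytokine, 3.57 ± 1.77 FPKM in the pancreas libraries labelled p53 KO. In i4F pancreas they measured 0.017 and 0.00813 FPKM, and in i4F Ink4a/Arf KO pancreas Il6 was listed at 0 in all 5 libraries.

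**Figure D1:**
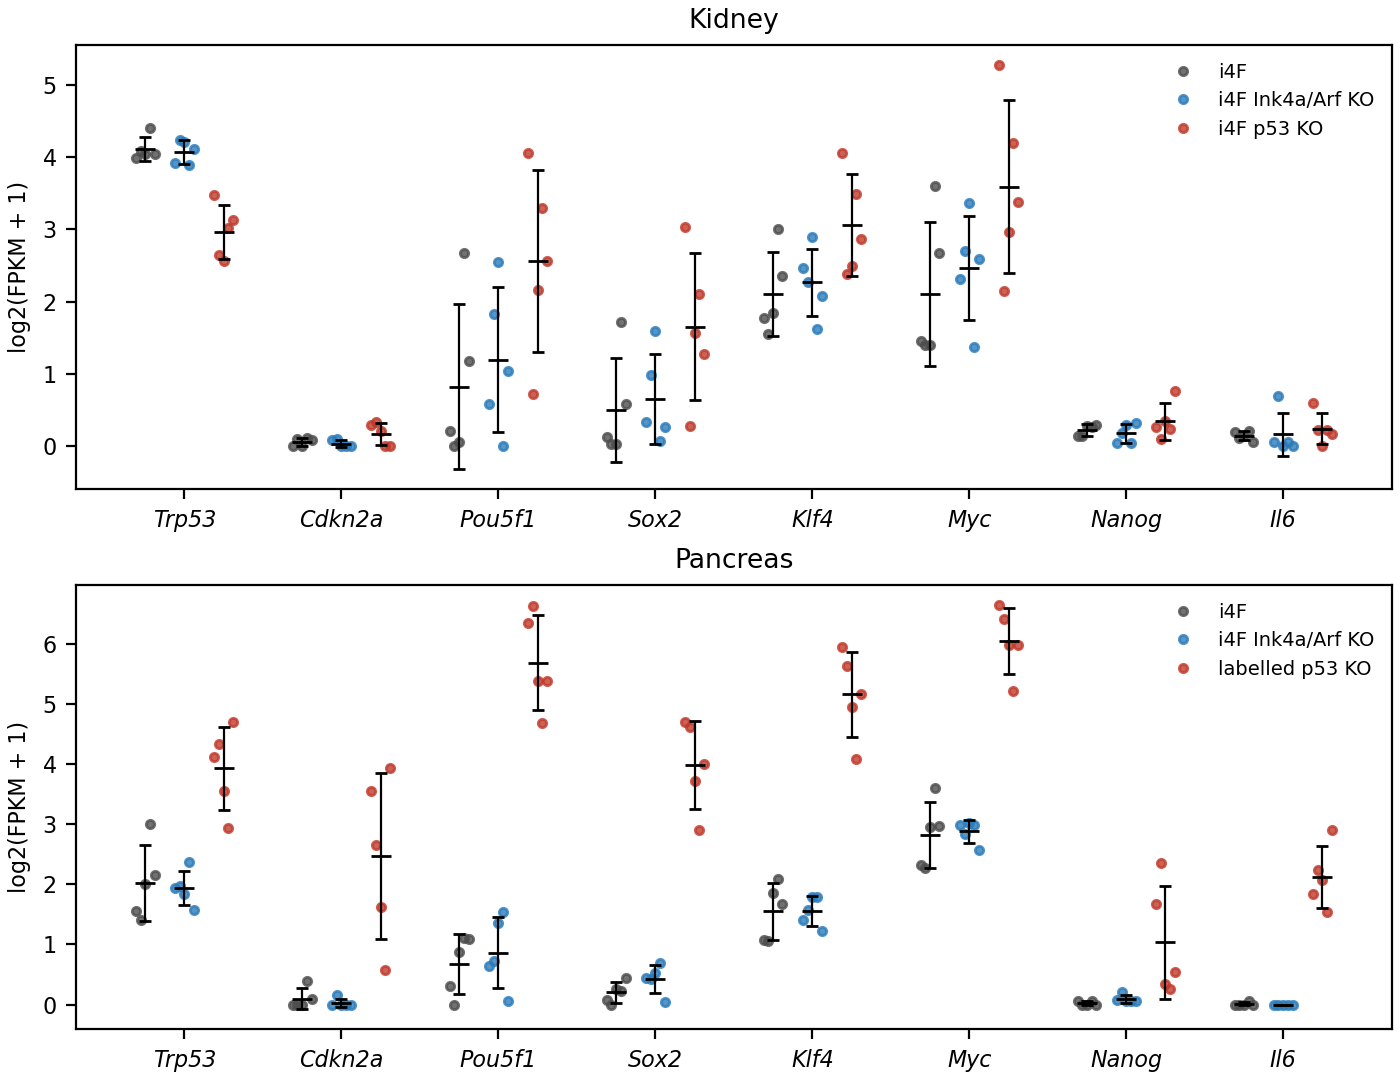
Level of 8 genes in each of 30 libraries as log2(FPKM + 1), kidney above and pancreas below; each point is 1 mouse, colours give the genotype, and bars are the mean and SD of 5 mice. Trp53 sits at 7.04 FPKM in kidney p53 KO against 16.4 in i4F, and at 15.6 against 3.4 in the pancreas.

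In the kidney without Ink4a/Arf, no single gene of 12431 passed the test against i4F, while 398 had an unadjusted p under 0.05 by limma. The smallest adjusted p was 0.739, for Plin2, a lipid droplet protein. Cdkn1a, the p53 target that encodes p21, measured 9.96 ± 6.98 FPKM against 7.40 ± 5.84 in i4F (adjusted p = 0.997). Of 34 tested gene lists 15 passed, 10 higher and 5 lower, and none passed with an estimated correlation (smallest adjusted p = 0.622 with an estimated correlation). The acinar cell list, transcripts of the enzyme-secreting cells of the pancreas, had the strongest shift, with a median log2 fold change of -2.16 over 27 members (adjusted p = 9.21e-23; adjusted p = 0.622 with an estimated correlation). None of its members passed over all genes and 16 were lower adjusted over the list alone. Without i4F replicate 5 the median was -1.52 (adjusted p = 1.75e-18). Among the i4F kidneys this replicate stood apart with 216 FPKM of Clps against 13.4 to 17.5 in the other 4, and in all 5 the acinar values kept pancreas proportions (r 0.915 to 0.981). All 27 mitosis members (median 0.17) and all 19 macrophage members (median 0.34) had positive values with no single call (adjusted p = 0.0017 and 0.000323). With an estimated correlation both had adjusted p = 0.801. Both rested on the female i4F Ink4a/Arf KO replicate 1: without it 7 of 19 macrophage members were positive (median -0.05, adjusted p = 0.682) and 16 of 21 mitosis members (0.07, adjusted p = 0.169). Mitosis also did not pass without i4F replicate 2 (adjusted p = 0.135). The 32 ribosomal protein members had a median of -0.22 (adjusted p = 1.77e-10; adjusted p = 0.801 with an estimated correlation). Female mice, by Xist and Ddx3y, gave i4F replicates 4 and 5 and i4F Ink4a/Arf KO replicate 1, and with Xist as a covariate 1 gene passed. With limma's array weights 2 genes passed.

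Against i4F, kidneys without p53 showed higher transcripts of neutrophils, 2 calcium-binding S100 proteins among them, and lower transcripts of several p53 targets. S100a8 measured 61.4 ± 21.3 FPKM in i4F p53 KO and 10.2 ± 2.68 in i4F (log2 fold change 2.43, SE 0.37, adjusted p = 0.0128), and S100a9 measured 45.9 ± 25 against 6.49 ± 1.22. Retnlg, also of the neutrophil list, rose by 2.18 (SE 0.30, adjusted p = 0.00628). These 3 of 5 tested neutrophil members passed over all genes and 5 adjusted over the list alone (adjusted p = 2.59e-08; adjusted p = 0.288 with an estimated correlation). Of 33 p53 target genes 3 fell and none rose: Ccng1, which encodes cyclin G1, at 21.8 ± 3 against 49.3 ± 9.88 FPKM (log2 fold change -1.13, SE 0.13, adjusted p = 0.00109), the DNA repair enzyme gene Mgmt (-1.25, SE 0.17, adjusted p = 0.00519) and the kinase gene Plk2 (-0.65, SE 0.11, adjusted p = 0.0227). Adjusted over the list alone 4 fell (adjusted p = 0.000593; adjusted p = 0.482 with an estimated correlation). Cdkn1a measured 7.03 ± 4.56 FPKM against 7.40 ± 5.84 in i4F (adjusted p = 0.992).

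Other kidney genes that changed without p53 included the complement gene C3 at 91.2 ± 58.8 against 8.26 ± 4.74 FPKM (log2 fold change 3.19, SE 0.56, adjusted p = 0.0262). C3 was the single call among 39 members of the kidney tubule injury list, of which 3 rose adjusted over the list alone (median 0.91, adjusted p = 2.82e-08; adjusted p = 0.619 with an estimated correlation). AA465934, a processed transcript on chromosome 11, measured 32.6 ± 12.6 against 3.35 ± 0.731 FPKM (log2 fold change 2.87, SE 0.27, adjusted p = 0.00039). Xaf1, of the interferon response list, rose by 1.36 (SE 0.15, adjusted p = 0.00109). It was the only one of 28 members called (2 adjusted over the list alone), and the list itself did not pass (adjusted p = 0.206). The organic anion transporter gene Slc22a7 fell from 140 ± 62.2 to 17.6 ± 17.7 FPKM (SE 0.59, adjusted p = 0.0243), the single call among 38 proximal tubule members, of which 2 fell adjusted over the list alone (adjusted p = 3.16e-06; adjusted p = 0.521 with an estimated correlation). Bdh1, an enzyme of ketone body metabolism, fell by 1.54 (SE 0.20, adjusted p = 0.00519). No oxidative phosphorylation member passed over all genes, yet all 34 had negative values and 20 were lower adjusted over the list alone, 0 after scaling (median -0.29, adjusted p = 3.82e-19; adjusted p = 0.482 with an estimated correlation). In the IL6 family signalling and response list 14 of 32 were higher adjusted over the list alone and 0 over all genes (median 0.48, adjusted p = 6.04e-09; adjusted p = 0.482 with an estimated correlation). All 5 p53 KO kidneys were male, and 3 of them held acinar transcripts of the pancreas, given with the next comparison.

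In all, 32 genes passed in kidney i4F p53 KO against i4F, 11 higher and 21 lower, and 1641 had an unadjusted p under 0.05. Without i4F p53 KO replicate 2 the count was 166 and without replicate 5 it was 69, and it was 11, 17 and 9 without replicates 1, 3 and 4; without i4F replicates 2, 3, 4 and 5 it was 12, 7, 15 and 10. Without the 4 kidney libraries above 100 FPKM of Clps, chosen after the data were seen, the count was 270, and with Xist as a covariate it was 244. With the replicate number as a block it was 17, of which 13 were among the 32. The calls of AA465934, Retnlg, Xaf1, Bdh1, Mgmt, Ccng1 and Trp53 held in every alternative in which they were tested, and others depended on single libraries or on the fit. C3 and S100a9 lost theirs without p53 KO replicate 1 or 4 or i4F replicate 2, 3 or 5 (log2 fold changes 2.88 to 3.37 and 2.42 to 2.56), and S100a8 without i4F replicate 3 (2.32). Slc22a7 lost it without p53 KO replicate 1 or 3 or any of i4F replicates 2 to 5 (-3.50 to -3.21) and Plk2 without p53 KO replicate 3 or 4 or any of i4F replicates 2 to 4 (-0.66 to -0.60). Calls were also lost with the replicate block (S100a8, Slc22a7 and Plk2), in males alone (Slc22a7 and Plk2), with only both groups fitted (C3, Slc22a7 and Plk2), with no filter (C3 and Slc22a7) and without the Clps libraries (Plk2).

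Set against i4F Ink4a/Arf KO, the same 5 p53 KO kidneys had lower transcripts of some p53 targets: 5 of 33 fell and none rose. Adjusted over the list alone 10 fell and 1 rose (camera adjusted p = 4.31e-05, and 0.545 with an estimated correlation). As the p53 KO libraries are shared, this is not independent of the comparison with i4F. Ccng1 measured 21.8 ± 3 against 64.3 ± 3.33 FPKM (log2 fold change -1.53, SE 0.13, adjusted p = 3.25e-05). Mgmt fell by 1.29, Trp53inp1 by 0.78, Zmat3 by 0.62 and Plk2 by 0.59. AA465934 rose by 3.29 (SE 0.27, adjusted p = 3.25e-05), Xaf1 by 1.45 (SE 0.15, adjusted p = 0.000352) and Plin2 from 12.8 ± 6.33 to 47.8 ± 21.5 FPKM (log2 fold change 1.83, adjusted p = 0.0137). Slc22a7 fell by 3.55 (SE 0.59, limma adjusted p = 0.029). Retnlg of the neutrophil list also passed, but its call was lost without any 1 of 12 libraries (log2 fold changes 1.45 to 1.79). In total 33 of 12431 genes passed, 13 higher and 20 lower, with 2232 at an unadjusted p under 0.05.

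Acinar transcripts of the pancreas were also higher in this comparison. Clps, the colipase gene, measured 129 ± 101 FPKM in p53 KO and 2.13 ± 2.94 in i4F Ink4a/Arf KO (log2 fold change 5.03, SE 0.89, adjusted p = 0.0407). Cela2a, an elastase gene, Zg16 of the secretory granules and Ctrb1, a chymotrypsinogen gene, also rose (4.91, 4.32 and 5.11). Of 27 tested acinar members 4 rose over all genes and 22 adjusted over the list alone (adjusted p = 6.68e-19; adjusted p = 0.545 with an estimated correlation). Clps stood at 220, 197 and 191 FPKM in p53 KO replicates 2, 3 and 4 and at 216 in i4F replicate 5, against 13.4 to 20 in i4F replicates 1 to 4 and p53 KO replicates 1 and 5. In i4F Ink4a/Arf KO it was 7.37 in replicate 5 and at most 1.15 in the others. With Clps as a covariate, chosen after the data were seen, 8 of the 33 calls were left and Cela2a and Zg16 turned to -0.21 and -0.23. Clps was higher in every p53 KO kidney than in any i4F Ink4a/Arf KO kidney, so this covariate can remove calls of any cause. Cela2a and Zg16 are acinar genes like Clps, so their turn tests nothing.

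The count of 33 also moved with single libraries. It was 326 without p53 KO replicate 2 and 15, 9 and 19 without replicates 3, 4 and 5. It was 21, 13, 9, 17 and 17 without i4F Ink4a/Arf KO replicates 1 to 5, and 11, 12 and 20 without i4F replicates 2, 3 and 4. The i4F libraries enter through the shared estimate of the spread and through the filter, which were not told apart. The calls of AA465934 and Ccng1 held in every alternative run, those of Mgmt, Xaf1 and Plin2 in every one that left out a single library. Other calls were lost with 1 library left out: Clps and Cela2a (4.70 to 5.03 and 4.58 to 4.91) without any of i4F Ink4a/Arf KO replicates 1 to 4, p53 KO replicate 3 or 4 or i4F replicate 2 or 3, and Cela2a also without i4F replicate 1 or 4. Ctrb1 (4.68 to 5.28) lost it without i4F Ink4a/Arf KO replicates 1 to 4, and Zg16, Zmat3 and Plk2 (4.01 to 4.69, -0.67 to -0.54 and -0.62 to -0.54) without replicates 1 to 5. These 4 also lost it without p53 KO replicates 3 to 5 or i4F replicates 1 to 4. Slc22a7 (-3.62 to -3.44) lost it without i4F Ink4a/Arf KO replicates 2 to 5, p53 KO replicate 3 or i4F replicate 2, and Trp53inp1 (-0.78 to -0.72) without i4F Ink4a/Arf KO replicates 3 to 5 or p53 KO replicate 3 or 4.

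**Figure D2:**
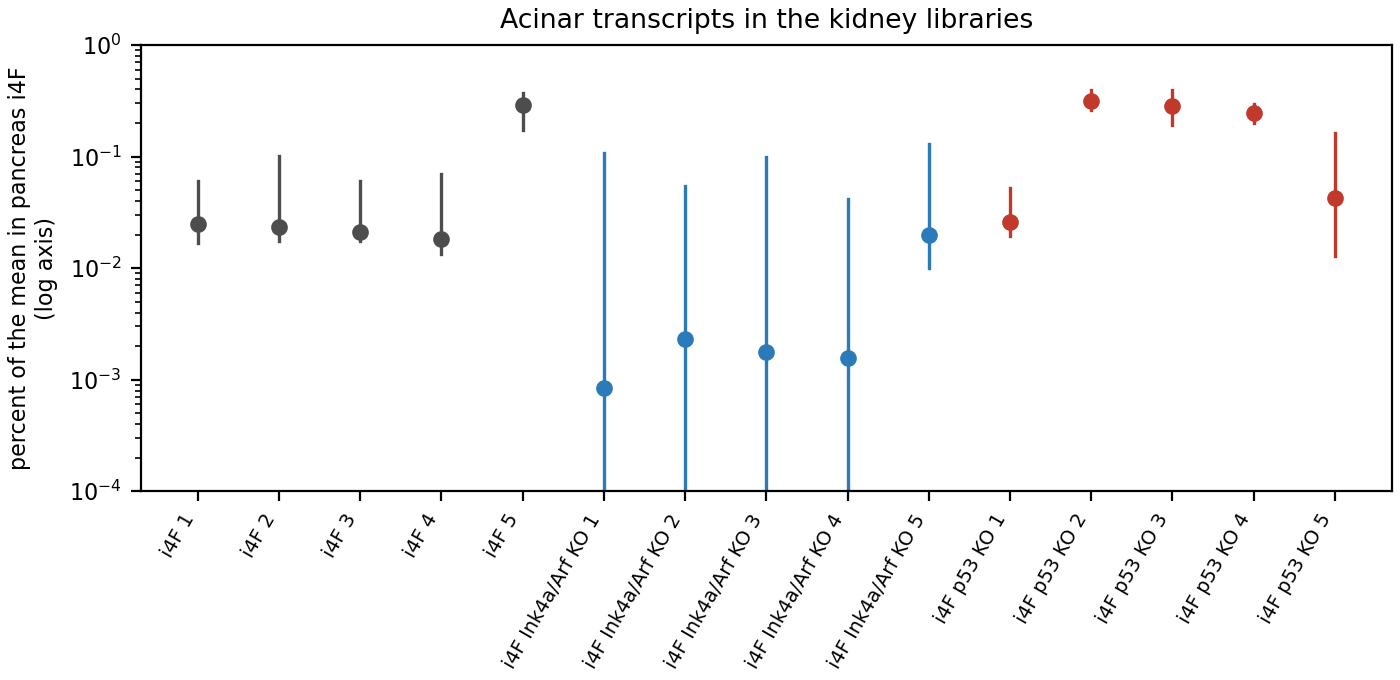
Acinar transcripts in the 15 kidney libraries, as the percent of their mean FPKM in the pancreas i4F libraries on a log axis; points are the median and lines the range over 16 acinar genes, with lower ends below the axis cut off. Medians reach 0.288% in i4F replicate 5 and 0.316%, 0.286% and 0.244% in p53 KO replicates 2, 3 and 4, and lie at 0.0427% or less in the other 11.

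In the pancreas without Ink4a/Arf, no gene of 10781 passed against i4F; 36 had an unadjusted p under 0.05 by limma and the smallest adjusted p was 1. Acinar transcripts made up 74.2 ± 5.48% of all FPKM in i4F Ink4a/Arf KO and 74.5 ± 5.25% in i4F. Abundant genes listed at 0 add nothing to these shares, and not in the same libraries. Prss2 and Cpa1 were at 0 in i4F replicate 5 and Cela1 in i4F replicate 1. Pnlip was at 0 in all but i4F Ink4a/Arf KO replicates 2 and 3, and Ctrb1 and Cela2a in every library of both groups. Cdkn1a measured 17.0 ± 5.02 FPKM and 15.4 ± 15.7 FPKM in i4F, and Myc 6.43 ± 0.921 and 6.50 ± 2.95 FPKM. Of 34 lists 12 passed, 10 higher and 2 lower, and none with an estimated correlation (smallest adjusted p = 0.234 with an estimated correlation). All 22 islet endocrine members had negative values, with a median of -0.66 (adjusted p = 7.6e-13; adjusted p = 0.47 with an estimated correlation) and no call over all genes or adjusted over the list alone. Of 32 ribosomal protein members 31 had positive values (median 0.16, adjusted p = 7.34e-14; adjusted p = 0.899 with an estimated correlation). With limma's array weights 286 genes passed, 90 higher and 196 lower. By Xist and Ddx3y, i4F replicates 3, 4 and 5 and i4F Ink4a/Arf KO replicate 1 were female, and in males alone 3 genes passed.

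The pancreas libraries labelled p53 KO differed from i4F in nearly every gene. Of 10781 genes 10070 passed, 9827 higher and 243 lower, with a median log2 fold change of 1.58. A gene below 1 FPKM in all other pancreas libraries was tested only if all 5 p53 KO libraries reached 1 FPKM. As deposited such a gene could only be higher in p53 KO. This adds to the counts of higher genes and list members in both comparisons with p53 KO. Without p53 KO replicate 1, 9698 genes were tested and 8863 passed. Acinar transcripts took 24.6 ± 21.6% of all FPKM in p53 KO, from 1.35% in replicate 5 to 54.5% in replicate 4, against 74.5 ± 5.25% in i4F. Changes were therefore also computed relative to the median gene, after median-of-ratios scaling. In that fit 7123 genes passed, 3637 higher and 3486 lower; of the 6513 called in both fits 3880 kept their direction. The fold changes below are given as deposited, then after scaling.

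Digestive enzyme genes of acinar cells fell. Ctrl, a chymotrypsin-like protease gene, measured 5289 ± 6957 FPKM against 44486 ± 5665 in i4F (log2 fold change -5.15, SE 1.17, adjusted p = 0.000465; -7.17 after scaling). Pla2g1b, a pancreatic phospholipase gene, fell by 4.38, Clps by 4.24 and the lipase gene Cel by 4.06, and Rbpjl, an acinar transcription factor gene, by 2.16. All 5 p53 KO values of each lay below every i4F value. Of 34 acinar members 22 fell and 3 rose, over all genes and adjusted over the list alone (adjusted p = 7.22e-64; adjusted p = 0.0271 with an estimated correlation). After scaling 26 fell and 2 rose, both counts also adjusted over the list alone (median -4.15; adjusted p = 0.432 with an estimated correlation). As deposited the 3 were Cela2a, Pnlip and Gata4, after scaling Cela2a and Pnlip. These 2 are listed at 0 in all 5 i4F libraries while reaching 66460 and 37587 FPKM in other pancreas libraries, so no change is read from them. Ctrb1, Try4, Cpa1, Cela1 and Prss2 were also listed at 0 in some libraries. Of 22 islet endocrine members 4 fell and 2 rose as deposited (4 and 1 adjusted over the list alone), and 14 fell and 1 rose after scaling (16 and 1). Among those that fell in both fits were Ero1lb, from 68.9 ± 17.6 to 17.6 ± 11.8 FPKM, and the transthyretin gene Ttr, from 14.2 ± 4.13 to 2.55 ± 1.82 FPKM. The islet list passed as deposited with an estimated correlation and not after scaling (adjusted p = 0.031 and 0.466 with an estimated correlation).

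Proliferation genes rose. All 35 mitosis members passed as deposited and after scaling, with a scaled median of 1.73 (adjusted p = 3.25e-16; adjusted p = 0.306 with an estimated correlation), as they did adjusted over the list alone. Plk1, a mitotic kinase gene, measured 16.0 ± 5.14 FPKM against 0.192 ± 0.134 in i4F (log2 fold change 3.78, SE 0.23; 2.41 after scaling), and Cdc20 26.4 ± 9.61 against 0.346 ± 0.201. Of 31 members of DNA replication and S phase 28 rose after scaling and 29 adjusted over the list alone (median 1.03, adjusted p = 4.67e-08; adjusted p = 0.381 with an estimated correlation), Uhrf1 among them at 15.3 ± 6.16 against 0.317 ± 0.272 FPKM.

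Keratins of stratified and embryonic epithelium had the highest scaled median of all lists. Krt13 measured 177 ± 81.4 FPKM against 0.38 ± 0.426 in i4F (log2 fold change 6.95, SE 0.29, adjusted p = 9.61e-11; 5.41 after scaling) and Krt6a 197 ± 102 against 0.321 ± 0.302 (7.08; 5.56 after scaling). Of 11 members of that list 9 rose and 1, Krt23, fell after scaling, over all genes and adjusted over the list alone (median 3.72, adjusted p = 5.12e-05; adjusted p = 0.281 with an estimated correlation). Krt23 had a positive value as deposited (0.34, adjusted p = 0.246) and -1.23 after scaling. Outside the list, Sprr2b, a gene of the cornified envelope, measured 401 ± 520 against 0.4 ± 0.666 FPKM, and the tight junction gene Cldn4 448 ± 324 against 1.48 ± 1.2 FPKM. Krt19, a keratin of duct cells, measured 689 ± 259 against 20.4 ± 13.9 FPKM (5.12; 3.11 after scaling). Of 5 tested pluripotency and early germ cell markers 4 rose after scaling, L1td1, Epcam, Cdh1 and Tfcp2l1 (1.72, 1.78, 1.23 and 0.52), and Lefty1 fell by 0.86, the same 4 and 1 adjusted over the list alone. The list did not pass (adjusted p = 0.111), and Epcam and Cdh1 are genes of epithelial adhesion.

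Fibroblast and macrophage transcripts rose as well. Of 32 members of fibroblasts and extracellular matrix 31 rose after scaling, 31 also adjusted over the list alone (median 2.40, adjusted p = 4.78e-09; adjusted p = 0.381 with an estimated correlation). Timp1, a metalloproteinase inhibitor gene, measured 392.4 ± 258 against 0.997 ± 0.780 FPKM (7.48; 5.83 after scaling) and the collagen cross-linking gene Lox 92.2 ± 72.7 against 0.686 ± 0.649. All 23 macrophage members rose in both fits and adjusted over the list alone (scaled median 1.90, adjusted p = 2.31e-07; adjusted p = 0.389 with an estimated correlation), Trem2 at 32.6 ± 17.5 against 0.753 ± 0.847 FPKM. Of 9 members of neutrophils and myeloid precursors 3 rose after scaling, also adjusted over the list alone, and the list did not pass (median 1.23, adjusted p = 0.111). All 16 endothelium members rose as deposited, also adjusted over the list alone (median 1.41), and after scaling the list went the other way, with 6 of 16 lower, 5 adjusted over the list alone, and none higher (median -0.21, adjusted p = 0.0645).

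Genes of the senescent secretome and of IL6 signalling rose in most members. Of 33 secreted factors 27 rose and 2, Egf and Vegfa, fell after scaling (28 and 2 adjusted over the list alone; median 1.16, adjusted p = 2.32e-06; adjusted p = 0.306 with an estimated correlation). Vegfa was higher as deposited (0.83) and lower after scaling (-1.01). The chemokine gene Ccl2 measured 55.5 ± 26.6 against 0.741 ± 0.744 FPKM (4.97; 3.42 after scaling). Il6 rose by 2.10 (SE 0.19, adjusted p = 1.23e-07) and by 1.16 after scaling. Of 29 members of IL6 family signalling and response 21 rose and 4 fell after scaling, also adjusted over the list alone (median 0.98, adjusted p = 0.000624; adjusted p = 0.306 with an estimated correlation). The iron-binding acute phase gene Lcn2 measured 618 ± 540 against 3.38 ± 2.95 FPKM. The 4 that fell after scaling were Lifr, Pim3, Fgl2 and Il11ra1 (-2.11, -1.70, -1.66 and -1.28), and the last 3 had positive values as deposited. Among 32 p53 targets 26 rose and none fell as deposited, also adjusted over the list alone (median 1.34), and 6 rose and 12 fell after scaling, over all genes and adjusted over the list alone (median -0.08, adjusted p = 0.353). Cdkn1a measured 74.9 ± 50.2 against 15.4 ± 15.7 FPKM (2.69, adjusted p = 0.000423), which did not pass after scaling (0.78, adjusted p = 0.187).

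The direction of the housekeeping lists depended on the scaling. Of 32 ribosomal protein members 31 rose as deposited and 32 fell after scaling (medians 0.91 and -1.14). Of 34 oxidative phosphorylation members 32 rose as deposited and 32 fell after scaling (medians 1.13 and -0.91). The counts were the same adjusted over the list alone, and after scaling both lists had adjusted p = 0.401 with an estimated correlation. Of 34 lists 16 passed as deposited and 21 after scaling; with an estimated correlation 4 passed as deposited, the acinar, islet endocrine, proximal tubule and distal nephron lists, and none after scaling.

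**Figure D3:**
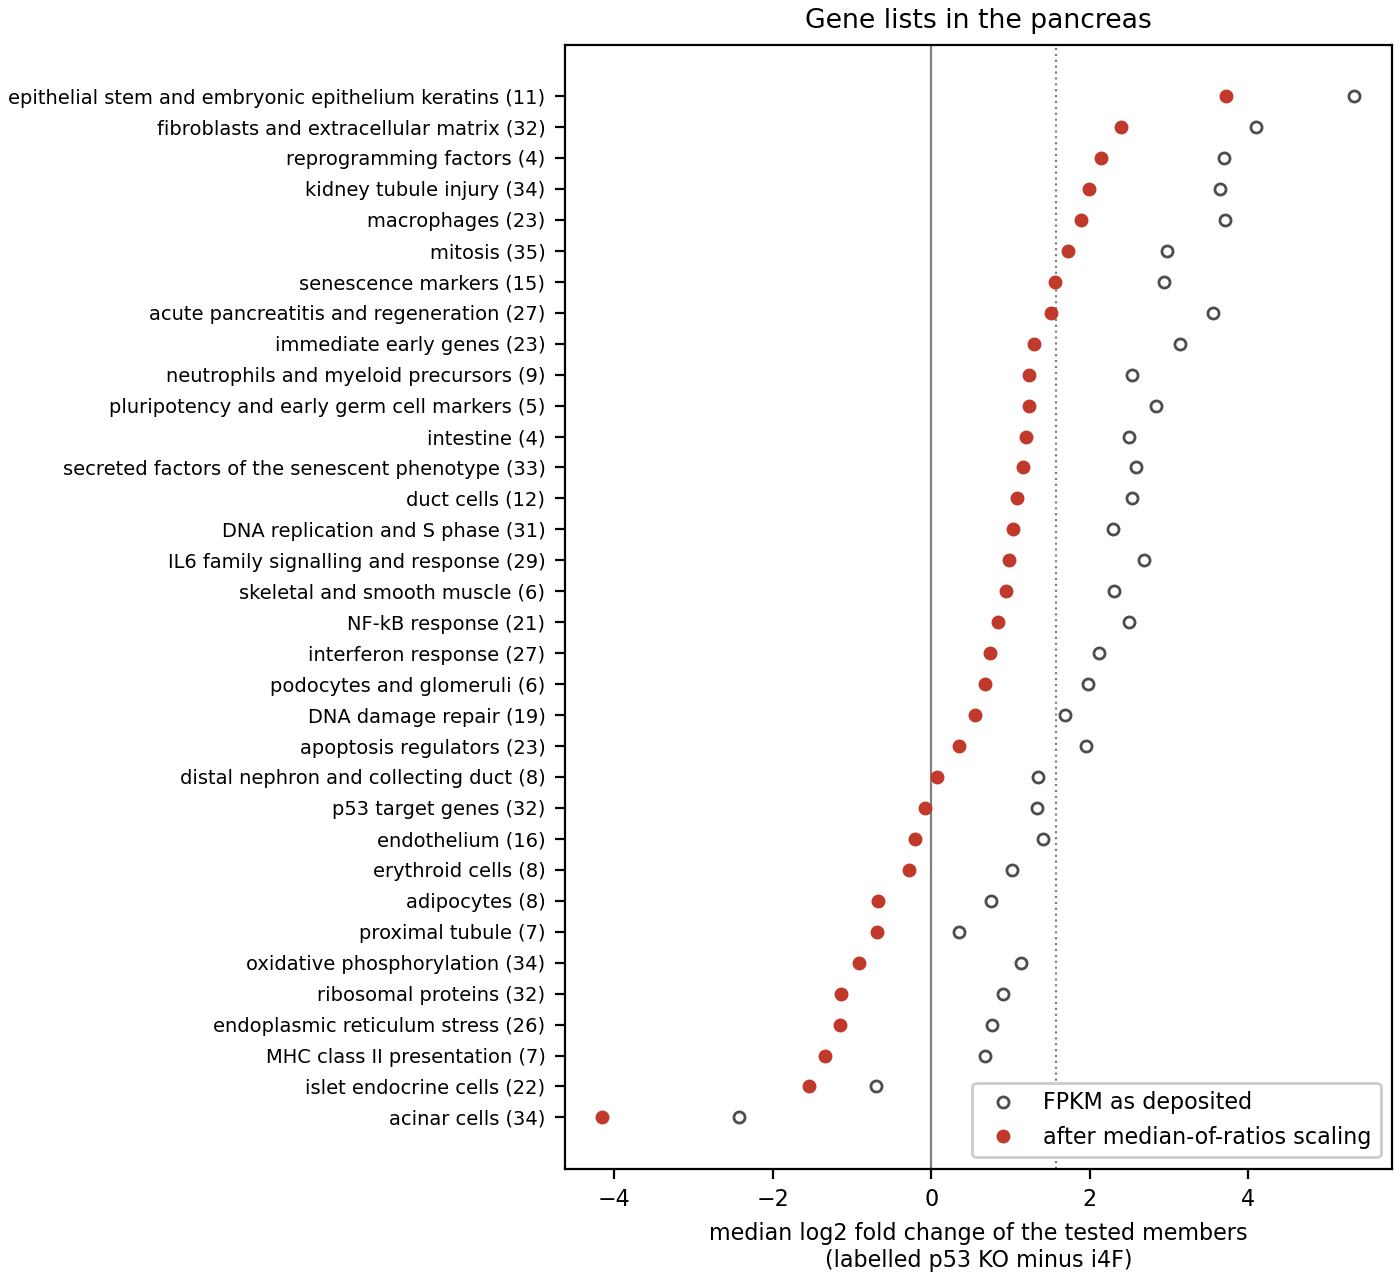
Median log2 fold change of each gene list, pancreas libraries labelled p53 KO minus i4F, with the number of tested members in parentheses; open circles are FPKM as deposited, filled circles values after median-of-ratios scaling, and the dotted line is the median of all genes as deposited (1.58). After scaling the medians run from -4.15 for acinar cells to 3.72 for the epithelial keratins.

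Against i4F Ink4a/Arf KO the libraries labelled p53 KO gave a like picture: 10103 of 10781 genes passed, 9891 higher and 212 lower, with a median of 1.66. After scaling 7319 passed, 3762 higher and 3557 lower. Plk1 measured 16.0 ± 5.14 against 0.32 ± 0.271 FPKM, the collagen gene Col1a1 1212 against 8.22 ± 2.97, the macrophage gene Cd68 86.9 ± 37.6 against 2.61 ± 0.656 and the duct keratin Krt7 239 ± 154 against 1.78 ± 0.468. Their log2 fold changes were 3.65, 6.53, 4.47 and 5.92, and 2.18, 4.44, 2.51 and 4.01 after scaling. Ctrc, a chymotrypsin gene, fell from 302 ± 31.5 to 51.8 ± 59.6 FPKM and the trefoil factor gene Tff2 by 3.96. After scaling 27 of 34 acinar members fell and 28 adjusted over the list alone, while 1, Cela2a, listed at 0 in the i4F Ink4a/Arf KO libraries, had a positive value. All 35 mitosis, all 23 macrophage and 31 of 32 fibroblast members rose after scaling and adjusted over the list alone (adjusted p = 0.349, 0.365 and 0.349 with an estimated correlation). Cdkn1a was higher as deposited (1.90, adjusted p = 0.0063) and not after scaling (-0.18, adjusted p = 0.762).

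The difference between tissues was tested directly as kidney effect minus pancreas effect in 13039 genes. For the Ink4a/Arf KO label no gene passed, and 83 had an unadjusted p under 0.05 by limma. For the p53 KO label 11244 genes passed, 218 with the higher effect in the kidney and 11026 in the pancreas, and 5558 passed after scaling, 2775 and 2783. Trp53 differed by -3.05 (SE 0.38, adjusted p = 1.96e-07) and by -1.33 after scaling (adjusted p = 1.89e-05). As deposited all 4 induced factors passed (Pou5f1 -3.27, Sox2 -2.62, Klf4 -2.65 and Myc -1.73). Of these, Sox2 differed by -1.29 and Klf4 by -0.90 after scaling (adjusted p = 0.035 and 0.0409), while Pou5f1 (-1.74, adjusted p = 0.0643) and Myc (0.18, adjusted p = 0.828) did not pass. C3 differed by 0.67 as deposited (adjusted p = 0.476) and by 2.62 after scaling (adjusted p = 0.00719), with pancreas changes of 2.52 and 0.55. Mgmt and Ccng1 differed as deposited (-1.19, adjusted p = 0.000291, and -1.74, adjusted p = 4.19e-05) and did not pass after scaling (0.31, adjusted p = 0.398, and 0.06, adjusted p = 0.838). Their pancreas changes were -0.06 and 0.61 as deposited and -1.57 and -1.22 after scaling.

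Both knockouts were compared with the same 5 i4F libraries, so their fold changes share that error. Across 12431 kidney genes the fold changes against i4F had r = 0.193, below the mean of 0.476 that unchanged groups gave in 100 simulations (5th to 95th percentile 0.127 to 0.773). With the i4F libraries split between the comparisons the mean r was -0.078 over 20 splits. In the pancreas r was 0.146 across 10781 genes, against 0.489 simulated (0.107 to 0.778) and 0.029 with split controls. The simulation held no genotype change, while 10070 of these genes passed for p53 KO, which can lower r whatever is shared. The covariance of the fold changes was 0.0371 in the pancreas, against 0.0354 simulated (0.00344 to 0.0771). In the kidney it was 0.0179 against 0.0344 (0.00731 to 0.0699), also inside the simulated range. Genes are not independent replicates.

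Across mice, the mean level of the pluripotency list was set against that of the secreted factor list, the genotype means removed, in 3 relations tested. The pluripotency mean took in listed genes below the filter for testing. Of its 32 members only 4 passed that filter in kidney and 5 in pancreas. Over 15 kidney libraries Pearson's r was 0.33 (permutation p = 0.285, adjusted 0.427) and Spearman's rho 0.42 (permutation p = 0.143, adjusted 0.215). Before the genotype means were removed r was 0.31 and rho 0.27 (permutation p = 0.259 and 0.327). Without the 2 libraries farthest from the median r was 0.65. Over all 15 it was 0.19 with a pseudocount of 0.1 and 0.06 after median-of-ratios scaling. Nanog against Il6 in kidney gave r = -0.15 (permutation p = 0.663) and rho = -0.21 (permutation p = 0.503), and r = -0.16 without the 2 farthest libraries. In the pancreas the libraries labelled p53 KO stood apart and were left out. In the 10 that remained the pluripotency mean ran only from 0.232 to 0.300 on the log2(FPKM + 1) scale, near the floor. A relation there says little about expressed pluripotency genes. Over the other 10 libraries r was 0.71 (permutation p = 0.0514, adjusted 0.154) and rho 0.78 (permutation p = 0.0132, adjusted 0.0397), with r = 0.61 without the 2 farthest. Before the genotype means were removed r was 0.68 and rho 0.87 (permutation p = 0.0197 and 0.00213). With the genotype means removed, r turned to -0.71 and rho to -0.59 after median-of-ratios scaling (permutation p adjusted 0.059 and 0.347), and with a pseudocount of 0.1 r was 0.83 and rho 0.78 (adjusted 0.0304 and 0.0542). Neither measure passed in all 3 settings.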

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

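The splits of the libraries were planned; the tests of library composition, of the genotype labels and of pancreas transcripts in kidney were chosen after the results were seen, and those of the acinar share and of AA465934 replaced earlier forms on the same values. Fold changes are on the log2(FPKM + 1) scale.

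The largest difference between the tissues lay in the libraries labelled p53 KO against i4F, where the test of the kidney minus the pancreas fold change called 11244 genes. Among named genes the differences were -3.05 for Trp53, -2.71 for Cdkn1a, -3.27 for Pou5f1, -2.62 for Sox2, -2.65 for Klf4, -1.73 for Myc and -2.01 for Il6. After scaling they were -1.33, -0.83, -1.74, -1.29, -0.90, 0.18 and -1.08, and those of Trp53, Sox2, Klf4 and Il6 passed the test. Of 100 splits 1 gave as many genes as the real one, which was the real one itself (highest of the others 10824). This is the smallest share that 100 splits can give, and it was not adjusted for the number of counts.

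Nearly all genes gained in the pancreas libraries labelled p53 KO, by a median of 1.58. The fall of the length-weighted acinar sum would supply a gain of 1.08 (SD 0.480 over 5 libraries) to the other genes, and whether a smaller acinar share gives the whole shift cannot be told apart, as 3 abundant acinar genes (Ctrb1, Pnlip and Cela2a) are listed at 0 in i4F. The scales also differ: 1.08 is a log2 ratio of sums, while 1.58 is on the log2(FPKM + 1) scale, which understates changes near 1 FPKM. The mean median-of-ratios factor, which has no such offset, was 2.87 in p53 KO and 0.669 in i4F. A loss of acinar cells alone, with the other cells unchanged both in their proportions and in their transcripts, was argued against. After scaling, the fibroblast list lay 2.60 above the endothelium list, beyond a spread of 1.32. These values do not show that the proportions changed. A change in which other cells were present, and a response of the remaining cells, stay open, since a bulk library does not part them. Splits of the libraries gave as many genes in 1 of 100 for p53 KO against i4F (10070; highest other 9965) and in 1 of 100 against i4F Ink4a/Arf KO (10103; highest other 9771), each the real split. No other split reached the real counts, and 1 of 100 is the smallest share these splits can give.

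Trp53 was not lower in the pancreas libraries labelled p53 KO, which raised the question of their genotype. Mice with intact Trp53 throughout stay open. Of 24 genes called in kidney p53 KO and tested in pancreas, Trp53 left out, 18 moved the same way after scaling (exact sign test, p = 0.0227). The sign test cannot decide this, as the genes are not independent and 7123 of all 10781 pancreas genes passed after scaling. Of the other 6, 3 were called the opposite way. The directions also rest on the scaling: Ccng1 and Plk2 were 0.61 and 0.54 as deposited and -1.22 and -1.34 after scaling. This test replaced one on a single gene after the values had been looked at. Single libraries with intact Trp53 stay open as well: the lowest scaled AA465934 value in these libraries, 3.50 FPKM, lay above the highest of the others, 1.37. However, so did 20.1% of all tested genes. Reads from parts of Trp53 outside the deletion may keep its FPKM up, since kidney p53 KO libraries kept 42.9% of the i4F level, but this and RNA from cells with an intact gene cannot be told apart without reads.

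Acinar transcripts in 4 kidney libraries (i4F replicate 5 and p53 KO replicates 2, 3 and 4) kept the proportions of the pancreas i4F means. So did lower amounts in others (r 0.915 to 0.946 in i4F replicates 1 to 4 and 0.971 in p53 KO replicate 1). The proportions of i4F pancreas were kept less in p53 KO replicate 5 (0.785) and i4F Ink4a/Arf KO (0.140 to 0.690). Each kidney library was also set against its closest single pancreas library, picked by the values. For p53 KO replicate 5 this was pancreas p53 KO replicate 2 (r 0.993). For i4F Ink4a/Arf KO replicate 5 it was pancreas p53 KO replicate 1 (r 0.942). In i4F Ink4a/Arf KO replicates 1 to 4 the closest r was 0.211 to 0.623. In the 4 the r of their log2 values over 16 acinar genes with the pancreas i4F means was 0.98 or more, up to 0.995, which is consistent with a small amount of pancreas RNA or reads in these libraries. Expression by kidney cells cannot be told apart from this by Ins2, an islet transcript, because its lowest value in the 4 libraries, 1.44 FPKM, lay below the highest of the other 11, 2.14 in i4F Ink4a/Arf KO replicate 5. That replicate held acinar transcripts as well (Clps 7.37 FPKM), so it is not a clean comparator. The next highest Ins2 value outside the 4 was 0.984 FPKM, in p53 KO replicate 5. Ins2 therefore does not decide the question. The acinar levels in the 4 libraries were 0.244% to 0.316% of those in pancreas, and the labels give no dissection or sequencing batch to test against.

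Trp53 in kidney i4F replicate 4, at 20.3 FPKM, stood apart from the other 4 i4F kidneys (14.8 to 16.0), with a gap of 0.763 of the group's range; of 55 pairs of a group and a measure tested this was the only one so far apart, and chance gives about 2.75.

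For Ink4a/Arf KO against i4F no gene was called, so that 100 of 100 splits gave as many by construction and nothing was tested (highest other 103 in kidney, 5 in pancreas and 23 in the difference between tissues). In kidney 3 of 100 splits gave as many genes as p53 KO against i4F (32, highest other 1457). For p53 KO against i4F Ink4a/Arf KO it was also 3 of 100 (33, highest other 438). Each share is under 1 in 20, not adjusted for the number of counts. In each comparison 2 other splits gave more genes than the real one, so chance was not excluded for these counts. The split with 1457 genes, picked as the highest of 100, set i4F replicates 4 and 5 with p53 KO replicates 1, 4 and 5 against the rest. What sets these libraries apart was not tested. For gene lists chance was not excluded: 29, 16 and 43 of 100 splits gave as many lists in kidney for i4F Ink4a/Arf KO (15; highest other 23), p53 KO (18; highest other 21) and p53 KO against i4F Ink4a/Arf KO (14; highest other 23). In pancreas 60, 19 and 8 of 100 did (12, 16 and 18 lists; highest other 18, 22 and 19).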

How the results depend on the processing

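The alternatives that left out genes listed at 0, females or kidney libraries above 100 FPKM of Clps, or took Clps as a covariate, were chosen after the data were seen; the others were planned. Where no cause is given, the cause was not tested. For kidney p53 KO against i4F (32 genes) the count was 57 with median-of-ratios scaling, 63 with quantile normalization, 1721 with array weights, 17 with replicate as a block, 244 with Xist, 13 with only both groups fitted, 270 without the Clps libraries and 134 with Clps as a covariate. Leaving out 1 library gave 7 (i4F replicate 3) to 166 (p53 KO replicate 2). For kidney p53 KO against i4F Ink4a/Arf KO (33) it was 61 with a pseudocount of 0.1, 12 with no filter, 51 with a filter of 5 FPKM, 69 scaled, 147 with quantile normalization, 3321 with array weights, 16 with the block, 313 with Xist, 5 with only both groups, 58 in males, 867 without the Clps libraries and 8 with the Clps covariate, and 9 to 326 without 1 library (i4F Ink4a/Arf KO replicate 3 or p53 KO replicate 4, and p53 KO replicate 2). Of the 32 calls, 32 were shared with array weights, 32 with Xist, 21 without the Clps libraries, 13 with the block, 14 in males and 12 with only both groups; of the 33, 33, 33, 29, 12, 21 and 5. For Ink4a/Arf KO against i4F (0 genes in each) array weights called 2 in kidney, 286 in pancreas and 127 in the difference between tissues, Xist and the Clps libraries left out 1 each in kidney, and males 3 in pancreas; without 1 library the counts were 0 to 1, 0 to 2 and 0 to 1. In pancreas p53 KO a filter of 5 FPKM, which tests fewer genes, gave 4825 against i4F and 4830 against i4F Ink4a/Arf KO; without 1 library the counts were 8863 to 10046 and 8915 to 10100. Genes past the threshold, difference between kidney and pancreas for the p53 KO label, were 5558 scaled, 5752 with quantile normalization and 10925 to 11561 without 1 library. Gene lists (15, 18 and 14 in kidney, 12, 16 and 18 in pancreas, for Ink4a/Arf KO against i4F, p53 KO against i4F and p53 KO against i4F Ink4a/Arf KO) were 0, 0, 0, 0, 4 and 2 with an estimated correlation and 0, 1, 3, 0, 29 and 30 with fry, which asks another question. Without 1 library, which for lists was run after the data were seen, the 15 lists became 11 (i4F Ink4a/Arf KO replicate 1 or i4F replicate 2) to 20 (i4F replicate 4). They were 7 for Ink4a/Arf KO against i4F in kidney with the Clps covariate and 26 for the libraries labelled p53 KO against i4F in pancreas with no filter. Among named genes, Cela2a and Zg16 in kidney p53 KO against i4F Ink4a/Arf KO turned to -0.21 and -0.23 with the Clps covariate. Clps itself separates these groups, so that covariate cannot part genotype from acinar transcripts. In pancreas p53 KO against i4F, scaling and quantile normalization turned Vegfa (-1.01 and -1.01), Krt23 (-1.23 and -1.26), Il11ra1 (-1.28 and -1.29), Fgl2 (-1.66 and -1.65), Pim3 (-1.70 and -1.61), Lefty1 (-0.86 and -1.06), Gata4 (-0.84 and -0.80) and Atm (-0.17 and -0.38), since both remove the shift of the median gene; Cdkn1a against i4F Ink4a/Arf KO turned to -0.18 with scaling. Array weights called Pou5f1, Sox2, Klf4 and Myc in both kidney p53 comparisons. In the other values of named genes the direction held, with the call lost in 42 of the values for kidney p53 KO against i4F, 196 against i4F Ink4a/Arf KO, and 12 and 3 in pancreas, and gained in 10 for pancreas p53 KO against i4F. The relation of pluripotency markers to secreted factors in pancreas was r = 0.83 with a pseudocount of 0.1 and -0.71 with scaling; r passed only with that pseudocount, and rho, which passed as deposited (adjusted p = 0.0397), did not with the pseudocount (0.0542) and turned to -0.59 with scaling (0.347). Depth per gene is unknown, so low levels carry an error that was not measured. The pluripotency mean is such a low level, as only 5 of its 32 members passed the filter in pancreas.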

Other observations

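The test on the neighbourhood of Trp53 was chosen after the result was seen.

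Further gene groups moved in the pancreas libraries labelled p53 KO against i4F after scaling. Of 26 endoplasmic reticulum stress genes 18 fell and 1, Atf3, rose (median -1.15, adjusted p = 0.000172; adjusted p = 0.399 with an estimated correlation). Both counts were the same adjusted over the list alone. As deposited 17 rose and 3 fell, Herpud1, Edem1 and Sel1l (-0.78, -0.54 and -1.04; 15 and 3 adjusted over the list alone). Without i4F replicate 4 the call of Herpud1 was lost (-0.57), and in males those of Herpud1 and Edem1 (-0.05 and -0.25). Of 27 interferon response genes 20 rose and none fell (21 adjusted over the list alone; median 0.75, adjusted p = 0.000156; adjusted p = 0.407 with an estimated correlation). Of 19 DNA damage repair genes 12 rose and 1, Atm, fell (median 0.55; adjusted p = 0.389 with an estimated correlation), and of 15 senescence markers 11 rose and 1, Igfbp5, fell (11 and 2 adjusted over the list alone; median 1.57; adjusted p = 0.381 with an estimated correlation). The immediate early gene Junb measured 100.2 ± 51.4 FPKM against 2.28 ± 1.17 in i4F.

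Transcripts of kidney were seen in some pancreas libraries. Umod, a transcript of the loop of Henle, stood at 2.02 FPKM in i4F replicate 5, 2.76 in i4F Ink4a/Arf KO replicate 5 and 2.26, 1.85 and 1.12 in p53 KO replicates 3, 4 and 5, and at under 1 FPKM in the others. Kap, a proximal tubule transcript, stood at 15.1 to 42.9 FPKM in these 5 libraries, and also at 13.2 in i4F replicate 1, 10.5 in i4F Ink4a/Arf KO replicate 2 and 0.298 in p53 KO replicate 2, and was listed at 0 in the other 7.

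A hypothesis was that genes near Trp53 differ in the p53 KO kidneys because the deleted allele carries a chromosome segment of another strain. Within 20 Mb of Trp53, 2 of 416 tested genes were called against i4F (Xaf1 and AA465934) and 26 of 10829 elsewhere, which does not part the shares (Fisher's exact test, two-sided, p = 0.278). Against i4F Ink4a/Arf KO the numbers were 3 and 28 (p = 0.106 by the same exact test). A segment may still account for single genes, and with so few calls the test leaves this open.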
